A study of Mus musculus with 6 samples.

How the data were processed

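Gene expression was measured in haematopoietic stem cells sorted from mouse bone marrow, per the labels by the gate c-Kit positive, lineage negative, Sca-1 positive and CD34 negative. The 6 arrays fell into 3 controls and 3 arrays of mice with floxed beta-catenin alleles and the Vav-Cre transgene, which drives recombination in blood-forming cells; these are called floxed arrays. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group were separate animals or pools, so the p-values measure the spread between these samples, which may be technical.

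Per the labels' protocols, cells were sorted into lysis buffer, RNA was extracted, and biotinylated cRNA was made from 100 ng of total RNA. The deposited table held log2 expression values for 241576 probe sets, between 2.44 and 14.53. The base of the logarithm was taken from the values, whose highest level stays below the limit of a 16-bit scanner only on a log2 scale. Per the submitters' processing notes, MAS5 was used, with no role or version named; background correction, summarisation and normalization are otherwise not given in the sources used here. The array medians lay between 7.56 and 7.65, and no further normalization was applied. Detection calls and scanner files were not used here, so no probe set could be called absent, and the number of arrays limits the precision.

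A platform annotation gave 1 gene symbol to 212097 probe sets, several to 4475 and none to 25004, and probe sets of the last 2 kinds were left out of tests of genes. Symbols were updated through a RefSeq table of the assembly GRCm38.p6, used for names alone; 17621 of 20416 symbols were current, 2742 were updated through a synonym and 53 matched neither. Coordinates are not given, because the annotation of the probe sets names no genome build.

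Probe sets were kept where their mean over the 6 arrays reached the median of such means, a log2 value of 7.60. Of these 120788 probe sets, 110361 had 1 gene. The value of a gene on an array was the median over its kept probe sets, which gave 14586 genes, because a gene had a median of 8 probe sets in the table. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are floxed minus control on the log2 scale. The same test was run on every kept probe set. The data.table package, version 1.17.8, read the values.

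The steps were tested on simulated values for the 14586 genes and 3 against 3 arrays, with 200 genes changed in each of 20 rounds. At a simulated log2 fold change of 1, 62.6% of the changed genes were recovered, at 2 it was 94% and at 4 it was 99.7%, and 4.06% of the calls were false. All 3 sizes were mixed among the 200 genes, so the larger changes eased the adjusted threshold for those at 1. Simulated noise was independent between genes and had the same SD in both groups. On the real arrays the median SD was 0.23 log2 in controls and 0.14 in floxed arrays, so these shares check the steps and do not give the power.

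The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The 27 lists covered antioxidant defence, oxidases that produce reactive oxygen species (ROS), targets of NRF2, FoxO and p53, DNA repair, canonical Wnt targets, Wnt pathway components, catenins and cadherins, HSC identity, quiescence, cell cycle, apoptosis regulators, oxidative phosphorylation, glycolysis and hypoxia, interferon response, and inflammation with NF-kB. Markers were listed for myeloid priming, mature granulocytes and macrophages, erythroid cells and megakaryocytes, B cells, T and NK cells, stroma and endothelium, and CD34 positive progenitors. Ribosomal proteins, immediate early and heat shock genes, and the sex of the animals were technical lists. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 27 lists; camera with an estimated correlation and fry stood beside it.

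Named genes were Ctnnb1; up to 8 genes per direction past the threshold, filled with the genes of smallest p among those with an absolute log2 fold change of at least 1 and named as not passing; the members of each list with the smallest p, and for marker and technical lists the member with the highest mean; and the gate genes Kit, Ly6a and Cd34. Predicted genes were passed over. Other list members named in the text as textbook examples were chosen after their values were seen.

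Alternatives were quantile normalization, equal array medians, no filter, a filter at the 75th percentile, the mean in place of the median of a gene's probe sets, eBayes without the trend or robust, array weights, the replicate number as a block, leaving out each array in turn and testing every probe set on its own. Added after the data were seen were limma's diffSplice test, the mean of the Ctnnb1 probe sets that did not pass, array weights without control replicate 2, and counts of Ctnnb1 probe sets under the alternatives.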

Results

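Expression was measured on 6 arrays of haematopoietic stem cells from mouse bone marrow, labelled as sorted for absence of surface CD34, 3 from controls and 3 from floxed, Vav-Cre positive mice. The comparison asks how transcript levels differ in stem cells of mice with floxed beta-catenin alleles and Vav-Cre. Beta-catenin, encoded by Ctnnb1, is a cell adhesion protein and transcriptional co-activator of canonical Wnt signalling. Loss of the protein was not measured here. The title of the series names oxidative stress, so genes of antioxidant defence are given in detail. Correlations across genes, which are not independent replicates, were 0.880 to 0.934 between control arrays and 0.962 to 0.972 between floxed arrays, and 0.915 to 0.963 between a control and a floxed array. The control arrays thus correlated no better with each other than with the floxed arrays. The median SD of a gene was 0.23 log2 in controls and 0.14 log2 in floxed arrays.

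Ctnnb1 signal fell in the floxed arrays on 5 probe sets that follow one another in probe-set number, and did not pass on the other 11 that were tested. On the last of them in number, the log2 value was 11.34 ± 0.08 (SD, n = 3) in controls and 4.44 ± 0.72 (SD, n = 3) in floxed arrays (log2 fold change −6.90, SE 0.34, limma adjusted p = 1.48e-05). The limma adjusted p of the 5 probe sets ran from 1.19e-05 to 0.00137, and each was lower in 3 of 3 floxed arrays than in any control. The log2 differences of the 5 ran from −6.90 to −2.51. Without detection calls the floxed values cannot be shown to lie above background, so the 5 differences were not ranked and do not measure how much transcript remained. The other 11 probe sets averaged 11.01 ± 0.10 (SD, n = 3) in controls and 11.03 ± 0.06 (SD, n = 3) in floxed arrays, with log2 fold changes from −0.28 to 0.48 and a smallest limma adjusted p of 0.975. The sources used here do not place the probe sets on exons, so whether the 5 lie in the deleted part was not determined, and a probe set outside that part says nothing about the deletion. Without any 1 of the control arrays 4 of the 5 passed, since the remaining probe set then lay below the filter on dim probe sets.

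The median over all 16 Ctnnb1 probe sets had a log2 fold change of −0.88 (SE 0.14) and did not pass in limma (adjusted p = 0.667). A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. With the mean of the probe sets in place of the median, Ctnnb1 passed (log2 fold change −1.64, limma adjusted p = 0.000269), as it did with array weights (−1.03, limma adjusted p = 0.00520). Over 15 alternatives for the gene value the log2 fold change ran from −1.64 to −0.16, the last with the 75th percentile filter, which removed the 5 affected probe sets, and the limma adjusted p from 0.000269 to 0.9998.

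**Figure D1:**
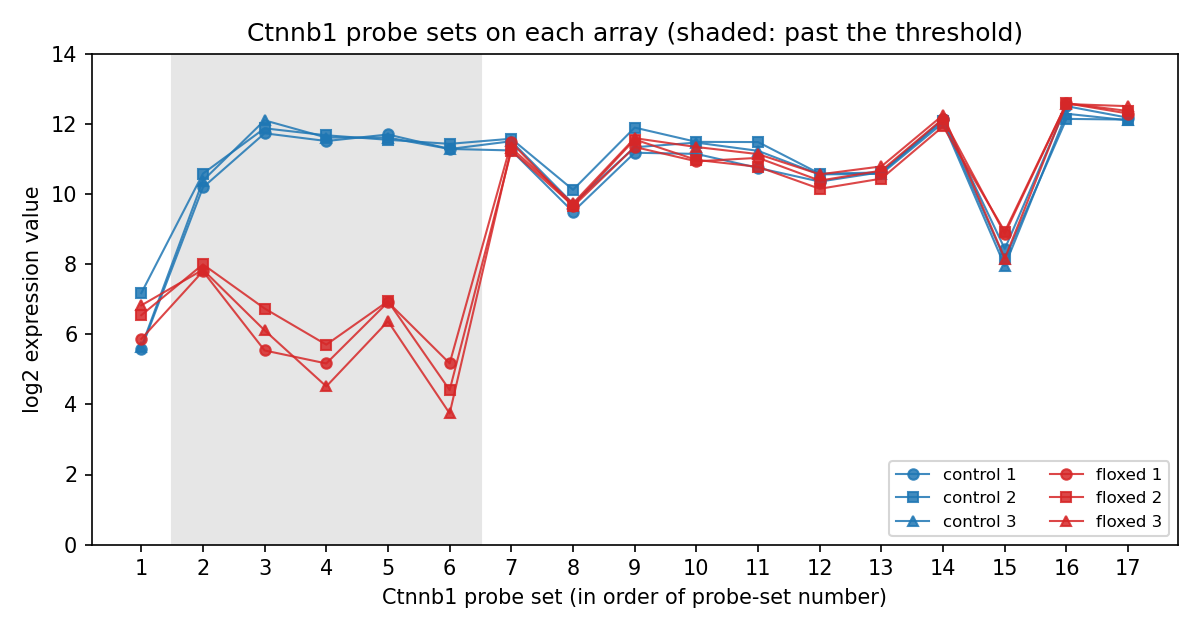
Log2 expression value (vertical axis) of the 17 Ctnnb1 probe sets in the order of their number (horizontal axis), with 1 line per array, controls in blue and floxed in red; shading marks the 5 probe sets past the threshold. At the last 4 of those the control values lie between 11.29 and 12.11 and the floxed values between 3.74 and 6.95, while the lines of both groups run close together outside the shading.

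No gene passed the threshold at gene level. In limma, 0 of 14586 genes passed (smallest adjusted p = 0.667). Of these, 540 genes (3.70%) had an unadjusted p under 0.05, 354 of them higher and 186 lower in floxed arrays. Groups did not overlap for 1231 genes (8.44%), where chance gives 10%. Among genes with an absolute log2 fold change of at least 1, Shcbp1, which encodes an SHC-binding protein, had 1.06 (SE 0.18, limma adjusted p = 0.667), the histone gene H2ac20 had 1.09 (SE 0.33) and Xist, the RNA of the inactive X chromosome, had 1.83 (SE 1.29). Xist turned to −0.23 without control replicate 2. On the lower side stood Sprr2a (−1.35), Nrg3 (−1.35), Slc9c1 (−1.34), Csprs (−1.32), Ugt1a1 (−1.12), Ighv2-2 (−1.08) and the neutrophil collagenase gene Mmp8 (−1.03). Each had a limma adjusted p of 0.999, and Csprs turned to 0.10 with array weights. Sprr2a (9.62), Nrg3 (10.23), Slc9c1 (11.34), Csprs (11.35) and Ugt1a1 (9.53) all had their highest value on control replicate 3. Each of them rested on 1 kept probe set, and their control SDs ran from 1.11 to 1.66 log2. Their differences thus lean on that array. Ighv2-2 was highest on control replicate 1 and Mmp8 on control replicate 2. Of the single probe sets, 5 of 120788 passed, all of Ctnnb1; 5255 (4.35%) had an unadjusted p under 0.05, and outside Ctnnb1 the smallest limma adjusted p was 0.936. The median 95% confidence interval of a gene reached 0.39 log2 to either side. Without control replicate 1, 2 genes passed, Rab9 (1.02) and Rny1 (1.37), chosen here after their values were seen. Array weights gave 404 genes, and limma's diffSplice test of probe sets within a gene gave 2, Ctnnb1 and Commd10.

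Genes of antioxidant defence did not pass as a group. Of 41 measured members, 27 were higher and 14 lower in floxed arrays, with a median log2 fold change of 0.05 (camera adjusted p = 0.377). The median was −0.01 with array weights and ran from 0.009 to 0.078 when 1 array was left out. Over all genes 0 members passed, and 0 when adjusted over the list alone (smallest limma adjusted p = 0.317). Of the 41, 39 had a 95% confidence interval within 1 log2 of 0. The peroxiredoxin genes Prdx1 and Prdx4, whose products reduce peroxides, had log2 fold changes of 0.47 (SE 0.16) and 0.49 (SE 0.17), and the mitochondrial Prdx3 had 0.50 (SE 0.22), none passing. The metallothionein genes Mt2 and Mt1, whose products bind metals, lay on the lower side at −0.65 (SE 0.28) and −0.45 (SE 0.25) and did not pass. The superoxide dismutase genes Sod1 and Sod2 had −0.13 and 0.11, catalase (Cat) had −0.21 and Gpx1 had −0.15. The oxidase list, with 10 of 13 members lower, had a camera adjusted p of 0.135 and passed without control replicate 3 (−0.09, adjusted p = 0.0443; 0.0443 to 0.521 over 15 alternatives). Its NADPH oxidase members Duox1 and Rac2 had −0.42 and −0.21. Targets of NRF2, FoxO and p53 each had a camera adjusted p of 0.983. Tkt and Pgd of the pentose phosphate pathway had 0.20 and −0.19, the chemokine receptor gene Ccr7 had −0.47, and Gtse1 and Gadd45a had −0.35 and 0.30. DNA repair genes had a camera adjusted p of 0.135, with Rad54l at 0.33 and Ercc2 at 0.29. That list, with a median of 0.13, passed in camera with no filter (0.14, adjusted p = 0.0130), with the mean of probe sets (0.11, adjusted p = 0.00606), without control replicate 1 (0.18, adjusted p = 0.0300) and without floxed replicate 3 (0.14, adjusted p = 0.0425). Over 15 alternatives its median ran from 0.00234 to 0.178 and its camera adjusted p from 0.00606 to 0.812. In these 5 lists 0 genes passed over all genes and 0 when adjusted over the list alone.

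Canonical Wnt targets were lower in floxed arrays as a group in camera at the preset correlation alone. Of 30 measured members, 22 were lower and 8 higher, with a median log2 fold change of −0.08 (camera adjusted p = 0.0253, and adjusted p = 0.750 with an estimated correlation). List means were 0.00771 to 0.0994 log2 in controls and −0.136 to 0.00588 in floxed arrays, which barely separated, and the median deviations of the list overlapped, at −0.03, 0.09 and 0.01 in controls and −0.11, 0.01 and 0.02 in floxed arrays. No member passed over all genes, and 0 passed when adjusted over the list alone. The receptor gene Tnfrsf19 had −0.66 (SE 0.22) and Nkd2, an inhibitor of the pathway, had −0.56 (SE 0.19). Axin2, Lef1, Tcf7, Ccnd1 and Myc had 0.07, −0.31, −0.09, 0.01 and 0.10. Control means were 8.46 and 8.56 log2 for Tnfrsf19 and Nkd2, and 7.90, 8.16, 8.37, 9.05 and 12.01 for the others in that order. After Myc the highest control means were those of Cd44 (10.86), Jun (10.56), Fgf18 (10.44) and Tcf4 (10.41). Their log2 fold changes were −0.20, −0.05, −0.17 and −0.02. Without detection calls, signal over background is unknown for the dimmer members, so the lower list cannot be read as lost Wnt output. The camera call was also lost without control replicate 2 (−0.06, adjusted p = 0.102), control replicate 3 (−0.06, adjusted p = 0.0840) and floxed replicate 1 (−0.06, adjusted p = 0.250). It was lost with no filter (−0.05, adjusted p = 0.113) and with array weights (−0.10, adjusted p = 0.0920). The median was −0.05 without control replicate 1 and −0.04 with the mean of probe sets, and the list passed under both. Over 15 alternatives the camera adjusted p ran from 0.00883 to 0.250. Wnt pathway components, with a camera adjusted p of 0.971, included Csnk1a1 (0.22) and Fzd3 (0.60). Catenins and cadherins, with a camera adjusted p of 0.828, included Ctnnal1 (0.31) and Cdh15 (−0.24). With no filter that list passed on the lower side, with a median of −0.11 against 0.02.

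Genes of the respiratory chain were higher in floxed arrays as a group in camera at the preset correlation alone. Of 63 members 49 were higher, with a median log2 fold change of 0.13 (camera adjusted p = 0.00128, and adjusted p = 0.863 with an estimated correlation). The complex I genes Ndufs6 and Ndufb6 had 0.76 (SE 0.13) and 0.55 (SE 0.15), and Ndufs6 was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.00756, and 0.667 over all genes). Ribosomal protein genes, a technical list, were higher for 33 of 38 members, with a median of 0.09 (camera adjusted p = 0.00960, and adjusted p = 0.750 with an estimated correlation), and 0 passed when adjusted over the list alone. The median of ribosomal proteins was 0.05 with quantile normalization and 0.06 with equal array medians. Rpl22, Rps4x and Rps20 had 0.36, 0.30 and 0.25. Cell cycle genes were higher for 31 of 46 members, with a median of 0.15 (camera adjusted p = 0.0131, and adjusted p = 0.863 with an estimated correlation), and 0 passed when adjusted over the list alone. The replication licensing inhibitor gene Gmnn had 0.55 (SE 0.15), the chromosomal passenger gene Cdca8 had 0.54 (SE 0.21) and the proliferation marker Mki67 had 0.21 (SE 0.11). Control replicate 3 had the lowest mean of all 6 arrays for both the respiratory chain (−0.24 log2) and the cell cycle list (−0.23 log2), and control replicate 1 was at 0.10 and 0.09, above 2 of the floxed arrays on each. Without control replicate 3 the camera adjusted p was 0.215 for the respiratory chain (0.03) and 0.378 for the cell cycle (0.06). Calls were lost for the respiratory chain without floxed replicate 3 (0.09, adjusted p = 0.0813). They were lost for ribosomal proteins without control replicate 2 (0.10, adjusted p = 0.109) and floxed replicate 3 (0.07, adjusted p = 0.0975), and for the cell cycle without control replicate 2 (0.11, adjusted p = 0.0805) and floxed replicate 1 (0.11, adjusted p = 0.0997). Over 15 alternatives the camera adjusted p ran from 5.92e-05 to 0.215, from 0.00397 to 0.109 and from 0.000462 to 0.378 for these 3 lists.

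Markers of mature granulocytes and macrophages, and of erythroid cells and megakaryocytes, were lower in floxed arrays in camera at the preset correlation alone. Of 22 granulocyte and macrophage genes, 18 were lower, with a median log2 fold change of −0.25 (camera adjusted p = 0.000199, and adjusted p = 0.750 with an estimated correlation). The granule protein genes Ngp, Mmp8 and Lcn2 had −0.88 (SE 0.28), −1.03 (SE 0.36) and −0.62 (SE 0.33), and S100a8 and S100a9 had −0.24 and −0.15. Of 21 erythroid and megakaryocyte genes, 19 were lower, with a median of −0.13 (camera adjusted p = 0.00960, and adjusted p = 0.863 with an estimated correlation). Epor, Alas2 and Car1 had −0.48, −0.40 and −0.14. In both lists 0 genes passed over all genes and 0 when adjusted over the list alone. The means of the granulocyte list were 0.20, 0.41 and −0.19 log2 on the control arrays and −0.35, −0.23 and 0.15 on the floxed arrays, so the groups overlapped. Without control replicate 2 the granulocyte list no longer passed (−0.12, adjusted p = 0.0592), and its median was −0.14 without floxed replicate 1 and −0.40 with array weights. The erythroid list did not pass without control replicate 2 (−0.03, adjusted p = 0.257), floxed replicate 1 (−0.12, adjusted p = 0.0997) or floxed replicate 2 (−0.06, adjusted p = 0.166), nor with no filter (−0.10, adjusted p = 0.0915). Its median was −0.22 without control replicate 1, −0.29 without floxed replicate 3 and −0.27 with array weights. Over 15 alternatives the camera adjusted p ran from 4.00e-09 to 0.0592 for the granulocyte list and from 5.66e-07 to 0.257 for the erythroid list.

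**Figure D2:**
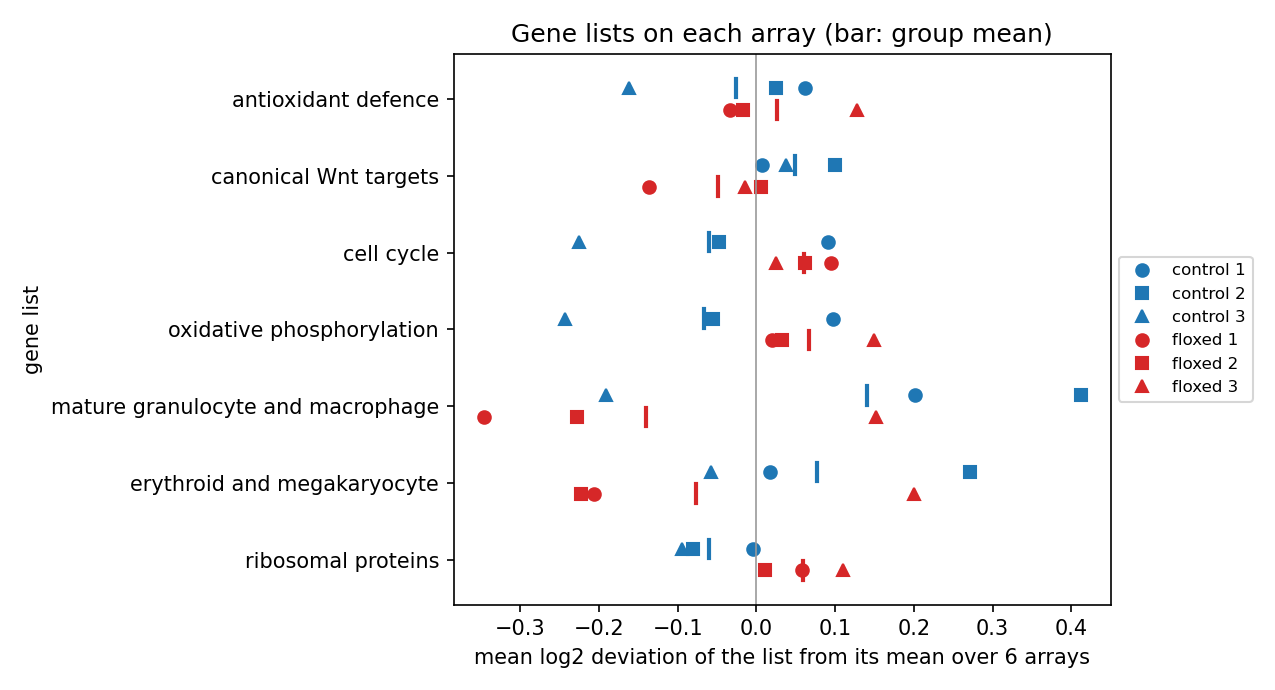
Mean deviation (log2, horizontal axis) of the genes of 7 lists from their mean over the 6 arrays, with 1 point per array, controls in blue and floxed in red, and a bar at each group mean. For the granulocyte list the control points span −0.19 to 0.41 and the floxed points −0.35 to 0.15, and for the respiratory chain control replicate 3 lies at −0.24.

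The gate genes and the remaining lists did not pass with all 6 arrays unweighted, the filter at the median and the median over a gene's probe sets. Other settings under which one of these lists passed are named here or with the processing alternatives. Cd34 had 12.68 ± 0.03 (SD, n = 3) in controls and 12.65 ± 0.04 (SD, n = 3) in floxed arrays (log2 fold change −0.03, 95% confidence interval −0.21 to 0.15). Those Cd34 values lie in the upper part of the range of the table, 2.44 to 14.53, although the label gives the cells as CD34 negative; the gate acts on surface protein, and these RNA values do not check it. Kit had a log2 fold change of −0.10 and Ly6a, which encodes Sca-1, had −0.02. The Ly6a value moved with single arrays. It was 0.28 without control replicate 1, −0.20 without control replicate 2 and −0.13 without control replicate 3. Without floxed replicates 1, 2 and 3 it was 0.04, 0.07 and −0.16. With array weights Ly6a had 0.23. The HSC identity list had a camera adjusted p of 0.135, with Hoxa9 at 0.37 and Hoxb4 at 0.48, and quiescence genes had 0.252, with Foxo3 at −0.20 and Egr1 at −0.35. CD34 positive progenitor markers had a camera adjusted p of 0.971, with Cd27 at −0.54 and Gpr171 at −0.49. Myeloid priming genes had 0.366, with Ly6c2 at −0.69 and Mpo at 0.05. For B cells the camera adjusted p was 0.440 (Vpreb1 −0.14, Cr2 −0.15, Flt3 0.01), for T and NK cells 0.135 (Cd4 −0.63, Prf1 −0.43, Nkg7 0.07) and for stroma and endothelium 0.202 (Cldn5 −0.50, Ibsp −0.22, Runx2 −0.16). Vpreb1, Cr2, Flt3, Nkg7 and Runx2 turned sign when some single array was left out, as did Mpo and the heat shock gene Hspa8. Nkg7 had 0.31 without control replicate 1 and −0.15 without control replicate 3. The B cell list had means of 0.63, 0.07 and −0.64 log2 on the control arrays, and those of the floxed arrays lay between, at −0.21, −0.10 and 0.25. Over 15 alternatives the median of the B cell list ran from −0.374 to 0.186, and that of myeloid priming from −0.249 to 0.144. Without control replicate 3 the B cell list passed (−0.37 against −0.06, camera adjusted p = 4.33e-05; 4.33e-05 to 0.721 over 15 alternatives), as did myeloid priming (−0.25 against −0.0013, adjusted p = 0.000360; 0.000360 to 0.620) and T and NK cells (−0.10 against −0.07, adjusted p = 0.0443). The T and NK list also passed without floxed replicate 3 (−0.17, adjusted p = 0.0255) and with the mean of probe sets (−0.11, adjusted p = 0.00520; 0.00520 to 0.611 over 15 alternatives). Without control replicate 1, camera passed HSC identity (0.17, adjusted p = 0.0261), stroma and endothelium (−0.14, adjusted p = 0.0387) and interferon response (0.11, adjusted p = 0.0473). HSC identity passed with array weights (0.09, adjusted p = 0.0163) and stroma with no filter (−0.10, adjusted p = 0.0418). Over 15 alternatives these 3 lists ran from 0.0163 to 0.956, from 0.0387 to 0.378 and from 0.0473 to 0.905. Apoptosis regulators had a camera adjusted p of 0.758 (Birc2 0.48, Cflar 0.36), and glycolysis and hypoxia genes 0.971 (Pkm 0.30, P4ha1 0.38). The camera adjusted p was 0.732 for interferon response genes (Ifi44 −0.39, Irgm1 0.38), 0.366 for inflammation genes (Ptgs2 −0.78, Ccl3 −0.28), 0.377 for immediate early and heat shock genes (Dnaja1 0.63, Dusp1 −0.41, Hspa8 0.05) and 0.135 for the genes that mark sex (Eif2s3y 0.56). Adjusted over the list alone, 0 genes of these lists passed in limma. The list of sex markers joins Xist with Y-linked genes, so a shared direction in camera does not measure a difference in sex. Of the 27 lists, 6 passed with the preset correlation, 3 higher and 3 lower, 0 with an estimated correlation (smallest adjusted p = 0.750) and 0 with fry (smallest adjusted p = 0.920). The estimated correlation was 0.518 for erythroid genes, 0.347 for the respiratory chain, 0.290 for granulocyte genes and 0.259 for the cell cycle. It was 0.0562 for Wnt targets and 0.0368 for ribosomal proteins. All 6 exceed the preset 0.01, so the preset p treats genes that move together as nearly independent. With fry 1 list had an unadjusted p under 0.05. Without control replicate 1 camera called 10 lists, without control replicate 2 it called 1 and without floxed replicate 1 it called 3.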

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

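The diffSplice test, the mean of the Ctnnb1 probe sets that did not pass and the counts of Ctnnb1 probe sets were chosen after the results were seen. Over 105 results and 1558 alternative values, 1478 stayed the same, 57 were stronger, 22 were weaker and 1 reversed. A gene or list was stronger where it passed newly, weaker where it no longer passed, and otherwise the same. It was reversed where its fold change or median turned sign and either value passed. A count was the same where it was equal or similar, and stronger or weaker where it was larger or smaller. Among results without a call the sign changed in 34 of 853 gene values and 47 of 252 list values, leaving out the eBayes and block settings, which cannot turn a sign. Of the list values, 54 of 405 are of eBayes settings, which leave camera as it is. The count of 0 genes became 2 with no filter (1 higher, Sva, and 1 lower, Mup10) and 1 with the mean of probe sets (Ctnnb1, −1.64, 1 lower). It became 404 with array weights (283 higher, 121 lower, Ctnnb1 −1.03). Leaving out 1 array gave 0 to 2 genes, 0 to 2 of them higher. Testing every probe set on its own gave 5 probe sets, all lower and all of the 1 gene Ctnnb1 (−4.88 for the one with the smallest p). The diffSplice test gave 2 genes, but it compares probe sets within a gene, and its p assumes independent probe sets. The 5 Ctnnb1 probe sets became 0 with the 75th percentile filter, which by its construction removed them as dim in floxed arrays, and 4 to 5 without 1 array; the other 11 averaged 0.0271, against −0.88 for the gene. Of 27 lists, 6 passed, but 0 with an estimated correlation and 0 with fry, and 1 to 10 without 1 array. Median log2 fold changes with no filter were −0.0511 for Wnt targets, −0.101 for erythroid genes and −0.109 for catenins and cadherins. For catenins and cadherins the reversal is one of the median, which was 0.02 with the main settings. The camera direction there was already lower, with a mean log2 fold change of −0.000588. With array weights Wnt targets had −0.0963 and antioxidant genes −0.0107, against 0.05. Granulocyte and erythroid genes had −0.401 and −0.270 with them, against −0.25 and −0.13. Without 1 array, medians ran from −0.109 to −0.0479 for Wnt targets, 0.0635 to 0.213 for the cell cycle, 0.0254 to 0.194 for the respiratory chain, −0.327 to −0.123 for granulocyte genes, −0.287 to −0.0336 for erythroid genes and 0.0679 to 0.110 for ribosomal proteins. The 6 called lists kept their sign in the 72 alternative values where it could change, and 17 values did not pass. Array weights and control replicate 3 are taken up under the other observations; elsewhere, apart from the filters on dim probe sets, the cause was not tested. As a replicate block, the shared replicate number gave 0 genes, Ctnnb1 at −0.88, 7 lists and 5 Ctnnb1 probe sets. The 7 lists were the 6 and the genes that mark sex (camera adjusted p = 0.0193), a list that joins Xist with Y-linked genes. Same-numbered arrays correlated at 0.953, 0.951 and 0.915. After the group mean of each gene was subtracted, they correlated at 0.198, −0.00365 and −0.243, so the numbers were not taken as pairs. On those centred values 1 of 3 control arrays had its best partner under its own number. Adding 16 to linear signal was not run, as the values were on a log scale. With no detection calls, signal over background is unknown for dim probe sets.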

Other observations

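The tests of granulocyte RNA and of control replicate 3 were chosen after the results were seen, as was the fit with array weights and without control replicate 2.

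Transcripts that mark the sex of the animals differed between arrays of one group; the values here are medians over all probe sets of a gene, dim ones included, and not over the kept ones as in the tests. Xist, the RNA of the inactive X chromosome, had a log2 value of 5.38 on control replicate 2, against 11.42 and 11.70 on control replicates 1 and 3 and 12.12, 11.12 and 10.75 on the floxed arrays, and its log2 fold change turned from 1.83 to −0.23 without that array. The Y-linked gene Eif2s3y had 7.07 on control replicate 3, against 8.61 and 8.91 on the other controls and 8.98, 9.13 and 8.74 on the floxed arrays. Kdm5d and Uty, also Y-linked, were likewise lowest on control replicate 3, at 7.10 and 6.89, against 8.49 and 8.09 on control replicate 1 and 8.36 and 8.56 on control replicate 2. On the floxed arrays Kdm5d had 8.22, 8.44 and 7.82, and Uty had 8.002, 8.12 and 8.19. Control replicate 1 and the 3 floxed arrays thus had neither the low Xist value of control replicate 2 nor the low Y-linked values of control replicate 3. High Xist beside Y-linked signal is what RNA of both sexes on 1 array would give, but each low level rests on 1 array. This pattern stood on all 3 floxed arrays and, among controls, on replicate 1 alone. The sex markers were thus uneven between the groups, and their part in the differences was not separated from genotype. The labels give neither the sex of the animals nor whether an array held RNA of more than 1 animal, and with pools the p-values would measure the spread between pools.

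Array weights called 404 genes where the unweighted fit called 0, among them Shcbp1 (0.96), Ndufs6 (0.72), Tnfrsf19 (−0.82) and Ngp (−1.09). Control replicate 2 carried a weight of 3.37 against 0.270 and 0.402 for the other controls. Xist, which was low on that array (5.38), was also called, at 4.88. Without control replicate 2 the weighted fit called 0 genes, so the calls may rest on that array in part. Over the 404 genes the median difference in the called direction was 0.64 log2 (median SE 0.13), and over the 398 still tested without that array 0.32 (median SE 0.25), with the sign kept in 392, which is partly built in because the genes were chosen for a difference between the same groups. Weights estimated from 3 arrays a group could also call genes by chance: a split that mixed the genotypes gave 1956 weighted calls, and 4 of 9 mixed splits gave more than 404. A genotype effect on these genes stays open.

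The lower level of mature granulocyte and macrophage genes may come from a different amount of RNA of such cells from one array to the next, although the lineage-negative gate would remove them. The mean of the list spanned 0.603 log2 within a group, against a difference of −0.28 between the groups. Other called lists also spread widely within a group. The erythroid means ran from −0.223 to 0.199 on floxed arrays, and those of the respiratory chain from −0.243 to 0.0966 on controls. The spread thus cannot tell granulocyte RNA from other differences between arrays. Its abundant members Ngp, Lyz2, Lcn2 and S100a9 had control values of 11.85, 11.39, 11.34 and 10.58 and floxed values of 10.97, 11.38, 10.72 and 10.43. Of its 22 measured genes, 3 are in other lists as well (Lcn2, Vcam1 and Hmox1), and how many the stem cells express was not tested. A lower level in floxed stem cells themselves stays open.

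The higher level of respiratory chain genes in floxed arrays may rest on control replicate 3 standing apart, which these arrays cannot settle. With quantile normalization the median of the list was 0.0912 (camera adjusted p = 0.000610). Over all genes, control replicate 1 had the lowest mean correlation with its own group (0.901) and the lowest array weight (0.270). Control replicate 3 had 0.907 and 0.402, the lowest mean correlation with the other arrays (0.915) and the lowest array median (7.56 log2). Without that array the median difference was 0.0254 log2 against 0.13 with all 6, but the array was singled out for its low value, so its removal had to shrink the difference; without control replicate 1 the median was 0.194 (camera adjusted p = 5.92e-05; 5.92e-05 to 0.215 over 15 alternatives). Ribosomal protein genes still passed in camera without that array, with a median of 0.0679 against 0.09 (adjusted p = 0.0114; 0.00397 to 0.109 over 15 alternatives). A genotype effect on either list stays open.

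The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, the genotype split gave 0 and the highest other split 8; since no split can give fewer than 0, all 10 gave as many by construction and the comparison shows nothing. For probe sets it gave 5, the highest other split 0, and 1 of 10 splits gave as many. For gene lists it gave 6, the highest other split 9, and 4 of 10 splits gave as many. The split with 8 genes and 9 lists set control replicates 1 and 2 with floxed replicate 3 against the rest; whether the samples have a structure beside the genotype was not tested.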
